A study of Oryza sativa Indica Group with 36 samples.

How the data were processed

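The deposited files hold RNA sequencing of rice leaves, with 1 file for each of 36 libraries. Per the labels, the uppermost fully expanded leaves of 45-day seedlings were taken under natural long days, RNA was isolated with TRIzol and treated with DNase, and libraries were made with a kit that does not mark the strand of origin. Because of that, reads of overlapping or antisense genes cannot be told apart, and members of near-identical families, among them the light-harvesting genes, can share reads. Libraries were grouped by their titles and sampling hours into 12 groups of 3, the parental cultivar Guangluai4 (GL) and an OsPRR37 overexpression line (OE) at each of 6 clock hours. The series' design text calls the 3 libraries of a group biological repeats; whether a replicate number marks the same plants or day across groups is not stated. The genotype field of GL replicate 3 at 0:00 names the overexpression line, while its title and the 18 and 18 libraries of the design text place it in GL. It was kept in GL, and the alternatives of leaving it out and of grouping it as OE were run.

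Per the submitters' processing notes, TopHat2, Cufflinks and Cuffdiff were used with the rice build IRGSP-1.0; their versions and settings are not given in the sources used here. Each deposited file lists 35477 loci, of which 33622 carry RAP identifiers, 1535 are loci that the authors' files call new genes, and 320 have other identifiers. The count column in the deposited files holds whole numbers, taken here to be expected counts that the authors rounded up. For 98.21% of counts above 0, the deposited normalised value divided by 1 factor per library lay at most 1 below the count. The sums of the deposited FPKM values (fragments scaled to transcript length and library size) differ between libraries. Whether the authors also rescaled these values between libraries was not tested. The deposited normalised counts were not used. Coordinates are those of the deposited files, on IRGSP-1.0.

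Total counts ran from 8065894 to 15769659 per library with a median of 12531717, and 22720 to 25520 loci had a count. Replicates of a group differed by more than sampling noise in every pair, with a chi-square per gene of 6.09 to 88.4 over genes with at least 20 counts in a pair, so no libraries were merged.

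Differential expression was tested on the deposited counts with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr on the 12 groups (minimum count 10, minimum total 15), which left 21772, and libraries were scaled by TMM. A quasi-likelihood F test (glmQLFit and glmQLFTest, trended dispersion) was run in 1 model of the 12 groups over all 36 libraries, with Benjamini-Hochberg adjustment and a threshold of 0.05. The contrasts were OE against GL averaged over the 6 hours, OE against GL at each hour, the genotype by hour interaction, and the change over the day within each genotype. A harmonic model with a 24-h period gave the rhythm tests, the difference in rhythm, the fitted peak hour and the fitted peak-to-trough range. Since 1 day was sampled, the period was assumed. Gene lists were tested with camera (limma 3.58.1) on voom values with a preset correlation of 0.01, and again with an estimated correlation. CPM values (counts scaled to library size) are on TMM-scaled library sizes, and folds are OE over GL.

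The gene lists were fixed from textbook knowledge before the data were examined, as were the comparisons with their tests, the alternatives and the rule for naming genes, apart from the alternatives named as added and the splits and tests that the closing section names as chosen after the results were seen. The files do not pair identifiers with names. Of 159 list members, 144 were in the files and the remaining 15 were not analysed here. A reference table of assembly ASM3414082v1, another build, placed 80 names on the same chromosome within 5 Mb of the listed identifier and held no name for 61; the 3 names it contradicted were dropped, which left 141 members. The rule named OsPRR37, every tested clock gene, floral inducer and floral repressor, and Hd1. The values of 1 gene that the rule named are left out of the text and figures; it stays in the counts of its list. From each other list it named at most 4 members with the smallest adjusted p in the averaged contrast. Outside the lists, loci without a name are given by identifier, at most 2 each way, for the largest rises and falls with the same sign at all 6 hours and a mean log2 CPM of at least 1, and for the largest changes of fitted range among genes with a called rhythm difference.

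The tests were tried on simulated data made from the real gene means and library sizes, with 200 genes changed in each of 3 ways. Over 21210 simulated genes kept, the averaged contrast recovered 85.1% of genes changed 1.5-fold and 100% of those changed 2-fold. At 16:00, 47.8% of genes changed 2-fold at that hour and 95.5% of those changed 4-fold were recovered. The interaction test recovered 17.9% of 2-fold and 84.8% of 4-fold changes confined to 16:00. The rhythm difference test recovered 86.5% of 200 genes with a 4-fold rhythm in GL and none in OE. Changed genes were picked from those with a mean log2 CPM over 1, and each gene was given the trended dispersion. Recovery was thus not tried for genes of lower level or of spread above the trend. The simulated libraries were drawn independently, with no difference between replicate numbers. Their genes were flat over the day apart from the changes, and the rhythms were pure cosines. Real libraries and daily profiles differ from this, so recovery in the real data may be lower.

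Alternatives were DESeq2 size factors, no filter, DESeq2 1.42.0 in place of edgeR, limma on log2(FPKM + 0.1) and log2(FPKM + 1) for genes with a mean FPKM of at least 0.5, the replicate number as a block, genotype and replicate number together as a random block, each library left out, an adjusted threshold of 0.01, limits on fold or range, and models of 1 hour alone. The random block was fitted with limma on voom values in place of edgeR, and limma on voom values without the block was not run. After the data were seen, fits on replicates 2 and 3 only and on counts reduced by 1 were added. Intervals and limits from counts cover counting error only.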

Results

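Leaf transcriptomes were measured by RNA sequencing in the indica rice cultivar Guangluai4 (GL) and in a line of it that overexpresses OsPRR37 (OE), a pseudo-response regulator of the circadian clock that delays flowering in long days. Leaves were taken every 4 h within a single day, from 4:00 to 0:00, with 3 replicates of each genotype at each hour, giving 18 GL and 18 OE libraries. Total counts were 8065894 to 15769659 per library. The 3 libraries of a group are biological repeats per the design text. The hour dominated the variation: the first and second principal components carried 34.9% and 23.6% of the variance, and they followed the hour with R squared values of 0.975 and 0.988. The third component (7.78%) followed the replicate number with an R squared of 0.649, and replicate 1 stood apart from replicates 2 and 3 in both genotypes. The fourth (5.64%) followed the genotype with an R squared of 0.742. Results from replicates 2 and 3 alone, chosen after seeing the data, are given beside the pooled counts and lists, and for single genes where a call differed.

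OsPRR37 (OS07G0695100; chromosome 7, 29616564 to 29629218) separated the genotypes in every library. In GL its level rose from 2.17 ± 0.698 CPM at 4:00 to 456 ± 43.9 CPM at 12:00 (SD, n = 3) and was back at 3.98 ± 0.283 CPM at 0:00. In OE it stayed between 842 ± 40.0 CPM at 4:00 and 1547 ± 276 CPM at 16:00 (SD, n = 3). Across single libraries GL ran from 1.49 to 505 CPM and OE from 800 to 1726 CPM, without overlap. The log2 fold change averaged over the 6 hours was 4.42 (SE 0.075; adjusted p = 2.1e-26, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, as for all adjusted p values of genes). It was 8.61 at 4:00 and 7.86 at 0:00; at 12:00, when the GL gene peaked, OE had 1482 ± 44.4 CPM (SD, n = 3). The fitted peak-to-trough range was 7.53 log2 units in GL and 0.90 in OE. A two-sided permutation test of log2(FPKM + 0.1) in 18 against 18 libraries gave p = 1e-05, the smallest that 100000 resamples can give. The resampling ignored the clock hour and the likeness of libraries that share a genotype and replicate number. It therefore treats the 36 libraries as independent. Counts of the transgene and of the resident gene were not separated. The GL library at 0:00 whose genotype field names the overexpression line had 3.81 CPM, beside 4.31 and 3.82 CPM in the other GL libraries of that hour and 854 to 985 CPM in OE.

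**Figure D1:**
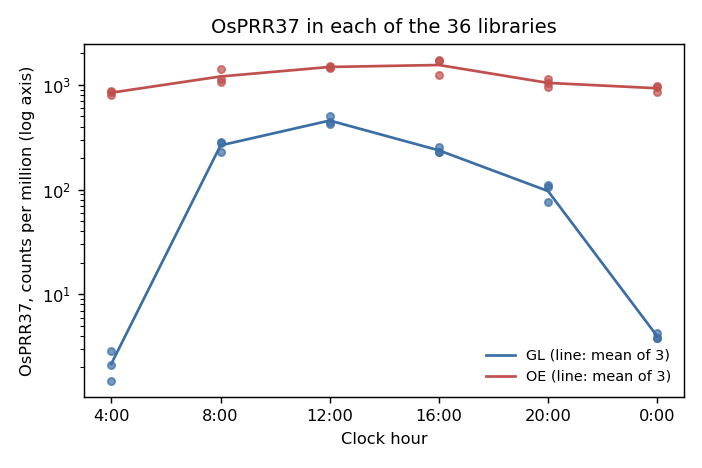
OsPRR37 level in CPM (log axis) against clock hour; points are the 36 libraries and lines join the means of 3 replicates of GL (blue) and OE (red). GL moves between 1.49 and 505 CPM over the day, and all OE libraries lie between 800 and 1726 CPM.

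The comparison of OE with GL averaged over the day asks which leaf transcripts differ between a line with high OsPRR37 at all hours and its parent. As 1 such line was used, effects of OsPRR37 cannot be told apart from other differences between the line and its parent. The flowering pathway showed the largest changes of any list. Ehd1 (OS10G0463400), a B-type response regulator that promotes flowering, fell from a mean of 8.91 to 0.177 CPM, a log2 change of -7.08 (SE 0.28). Ehd1 had 33 counts over the OE libraries, with 0 in 11 of the 18, so its log2 change leans on fitted values near the floor. The ratio of its summed counts, GL over OE and scaled to depth, was 56.5. Under other settings its log2 change ran from -7.16 to -2.50. OsMADS14 (OS03G0752800), a floral identity MADS-box gene, fell from 326 to 0.594 CPM (log2 -9.05, SE 0.24). OsMADS15 (OS07G0108900) had 158 counts over the GL libraries and 0 over the OE libraries, at least 59.1-fold lower against a limit of 3 counts over the OE group. OsMADS18 (OS07G0605200) fell by 1.68 on the log2 scale (SE 0.05). Adjusted p values of these 4 genes were between 3.2e-21 and 1.1e-05 (edgeR). Among the 10 tested floral inducers 5 fell and 3 rose. The rises were OsMADS50 (log2 0.71, SE 0.08), a MADS-box inducer of flowering in long days, OsMADS51 (log2 0.24, SE 0.05) and DTH2 (log2 0.22, SE 0.08). Adjusted over the list alone, 8 of 10 passed. OsDof12 (log2 0.03) and Ehd2 (log2 0.36) did not pass. The list as a whole lay lower in OE (camera adjusted p = 0.0018, and adjusted p = 0.022 with an estimated correlation; 0.013 in replicates 2 and 3). DTH2 did not pass with replicates 2 and 3 alone (log2 0.13, adjusted p = 0.11; 0.032 to 0.11 over its alternatives), and its call was lost in 19 of the 36 fits that left out 1 library.

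Floral repressors changed in both directions. Of 9 tested, 4 fell: OsCOL10 (OS03G0711100; log2 -1.43, SE 0.10), OsCOL4 (OS02G0610500; log2 -0.98, SE 0.10), OsCO3 (log2 -0.24, SE 0.09) and OsMADS56 (log2 -0.18, SE 0.05). OsCOL13 (OS07G0667300) rose (log2 0.76, SE 0.09), while DTH8 (log2 -0.01), Hd6 (log2 -0.03), Hd16 (log2 0.02) and Se14 (log2 0.00288) did not pass. Adjusted over the list alone, 5 of 9 passed, and camera gave an adjusted p of 0.16 for the list. The call of OsCO3 had an adjusted p of 0.048 and was lost in 21 of the 36 fits that left out 1 library. Hd1 (OS06G0275000), the rice CONSTANS homologue, had a higher mean of log2 levels over the hours in OE (log2 0.43, SE 0.13; adjusted p = 0.018), which came from its low hours, while its mean level was 10.9 CPM in GL and 9.36 CPM in OE. With limma on log2(FPKM + 1) Hd1 did not pass (log2 0.16, adjusted p = 0.25; 9.2e-04 to 0.25 over its alternatives).

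**Figure D2:**
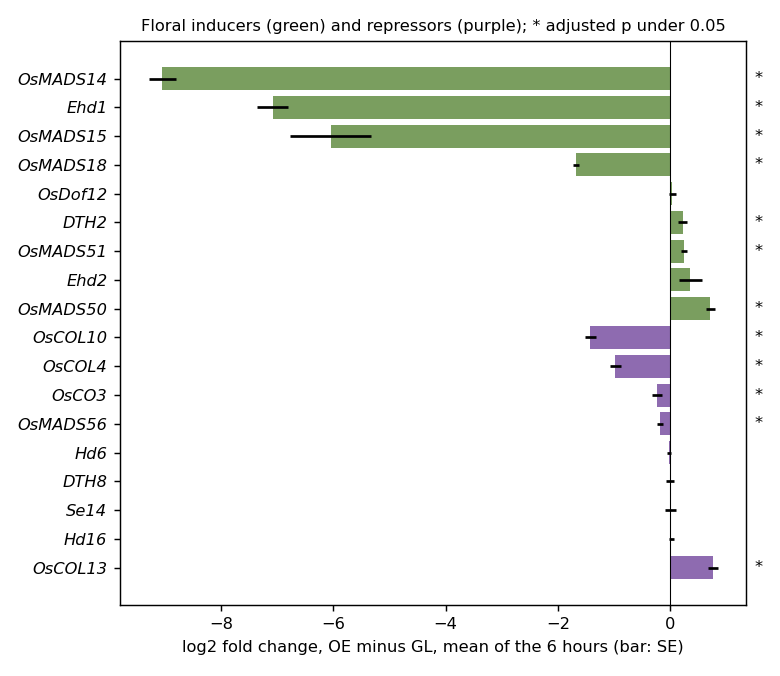
Log2 fold change of OE over GL, averaged over the 6 hours, for 9 floral inducers (green) and 9 repressors (purple), with SE bars and an asterisk where the adjusted p passed 0.05. OsMADS14 and Ehd1 lie at -9.05 and -7.08, and Ehd1 had 0 counts in 11 of the 18 OE libraries. The bar of OsMADS15 (-6.05) is a fitted value for a gene with 0 counts in OE.

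Within the circadian clock list (12 tested besides OsPRR37), 3 genes fell and 2 rose. OsLHY (OS08G0157600), the morning MYB factor, fell by 0.73 on the log2 scale in the average over the hours (SE 0.12; adjusted p = 3.6e-05). By single hours it passed at 4:00 (log2 -1.07) and 16:00 (log2 -1.05). At its 8:00 maximum it had 6898 ± 800 CPM in GL and 4938 ± 538 CPM in OE (SD, n = 3). That difference did not pass (log2 -0.48, edgeR adjusted p = 0.42). OsPRR73 fell (log2 -0.39, SE 0.07), as did OsPRR95 (log2 -0.36, SE 0.10). OsLUX (OS01G0971800), an evening complex gene, rose by 1.22 (SE 0.16; adjusted p = 2.0e-06), and OsPRR1 (OS02G0618200), the rice TOC1 homologue, rose by 0.42 in the mean of log2 levels (SE 0.06; adjusted p = 3.0e-06). The OsPRR1 rise came from its low hours, and its mean level was 61.0 CPM in GL and 55.6 CPM in OE. OsLUX passed at 4:00, 12:00 and 0:00, when its GL level was low (0.897 to 12.0 CPM). At 16:00 and 20:00, its highest hours, log2 values of 0.48 and 0.23 did not pass. The mean level of OsLUX was 90 CPM in GL and 124 CPM in OE. OsGI, OsELF3-1, OsELF4a, OsFKF1, OsPRR59, OsZTL1 and OsZTL2 did not pass, with log2 changes of -0.13, -0.12, -0.87, 0.42, 0.08, -0.13 and -0.07. Adjusted over the list alone, 5 of 12 passed, and camera gave an adjusted p of 0.66. With replicates 2 and 3 alone, OsGI (log2 -0.27), OsELF3-1 (log2 -0.21) and OsZTL1 (log2 -0.18) also passed.

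**Figure D3:**
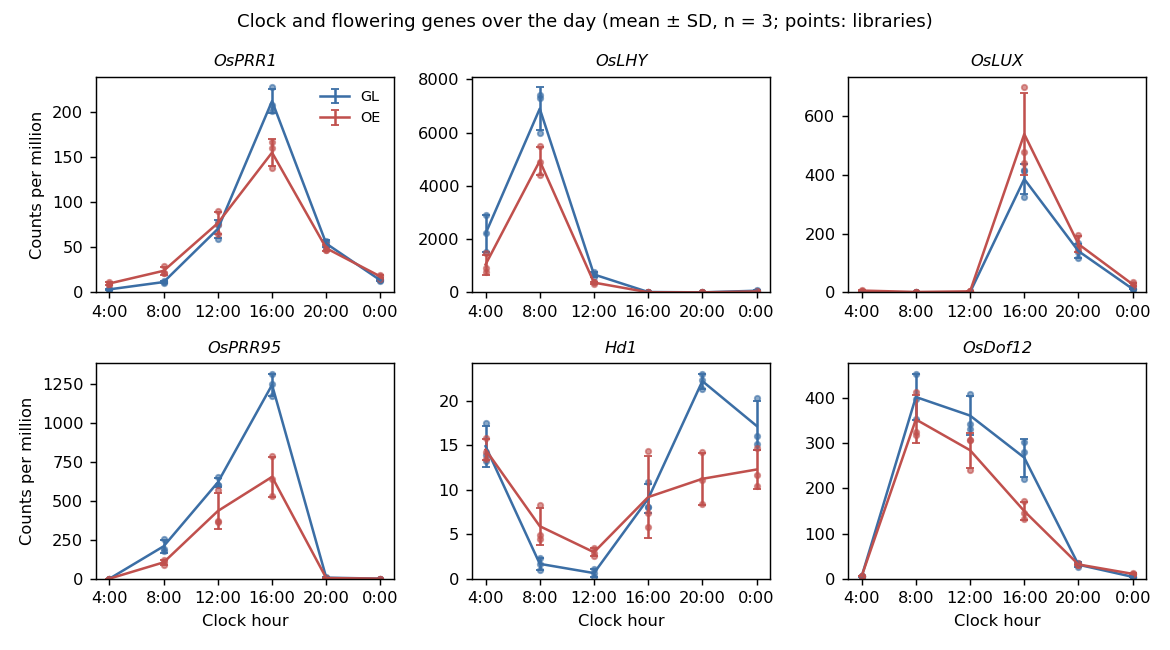
Level in CPM against clock hour for 6 clock and flowering genes in GL (blue) and OE (red); lines and bars are the mean ± SD of 3 replicates and points are libraries. OsLHY at 8:00 stands at 6898 CPM in GL and 4938 CPM in OE, and Hd1 at 20:00 at 22.2 and 11.3 CPM. Neither of these differences passed at its hour.

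Photosynthetic antenna genes were lower in OE in the average over the hours. Of 13 tested light-harvesting chlorophyll-binding genes, 10 fell and 0 rose, with a median log2 change of -0.73; 12 passed when adjusted over the list alone. The 4 with the smallest p were OS08G0435900 (log2 -1.04, SE 0.12), OS02G0197600 (log2 -0.73, SE 0.09), OS06G0320500 (log2 -0.81, SE 0.11) and OS07G0562700 (log2 -0.89, SE 0.13). By single hours, 9 fell at 4:00, 5 at 20:00 and 3 at 0:00. At 8:00, 12:00 and 16:00 edgeR called 0, with 0, 1 and 2 at an unadjusted p under 0.05. The mean level of OS08G0435900, which weights the hours of high expression, was 5280 CPM in GL and 3790 CPM in OE. Members of this family can share reads. Camera gave an adjusted p of 5.9e-09, and an adjusted p = 0.17 with an estimated correlation. Among 8 chlorophyll synthesis genes 3 fell, namely OsPORA (log2 -1.41, SE 0.24) and OsPORB (log2 -0.51, SE 0.10), which encode protochlorophyllide oxidoreductases, and OsDVR (log2 -0.48, SE 0.15), a divinyl reductase; OsHEMA1 (log2 -0.28) did not pass, but did in replicates 2 and 3 alone (log2 -0.34, adjusted p = 0.040). Camera gave an adjusted p of 0.015, and an adjusted p = 0.54 with an estimated correlation. Adjusted over the list alone, 4 of 8 passed. Both lists also stood higher in replicate 1 than in replicates 2 and 3, by medians of 0.24 and 0.25 (log2) in GL and 0.50 and 0.52 in OE. In replicates 2 and 3 alone their camera adjusted p values were 2.9e-09 and 1.5e-04 with the preset correlation. An estimated correlation was not run there.

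Starch genes fell in part: OsGBSSII (OS07G0412100), the leaf granule-bound starch synthase, by 1.71 (SE 0.14), OsSSI by 0.66 (SE 0.12), OsSSIIb by 0.58 (SE 0.10) and OsPHO1, a plastid starch phosphorylase, by 0.52 (SE 0.14) on the log2 scale. These were 4 of 13 tested starch and sucrose genes, 5 passed when adjusted over the list alone, and the list itself gave an adjusted p of 0.16, or 0.018 in replicates 2 and 3, and an adjusted p = 0.83 with an estimated correlation over all libraries. The starch and sucrose list stood higher in replicate 1 by medians of 0.28 (GL) and 0.46 (OE) log2 units. Jasmonate genes rose in 5 of 6 cases, among them OsOPR7 (log2 0.32, SE 0.05), OsAOS2 (2.83-fold, SE 0.46 on the log2 scale), both of jasmonate synthesis, and the repressor genes OsJAZ11 (log2 0.80, SE 0.24) and OsJAZ12 (log2 0.69, SE 0.25). Adjusted over the list alone the number was also 5 of 6. These counts are for the average over the hours. At 16:00 edgeR called 3 of the 6, with a median log2 change of 1.4. At each other hour it called 0, with medians from -0.0575 to 0.576. Camera gave an adjusted p of 0.012, and an adjusted p = 0.21 with an estimated correlation. The call of OsJAZ12 was lost in 17 of the fits that left out 1 library, and those of OsAOS2, OsJAZ11 and OsJAZ12 with limma on log2(FPKM + 0.1). OsAOS2 did not pass with limma on log2(FPKM + 1) (log2 0.39) or without OE replicate 3 at 4:00 (log2 1.03).

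Among 7 gibberellin genes 1 fell and 1 rose. SD1 (OS01G0883800), the gibberellin 20-oxidase of the semidwarf locus, fell by 2.04 on the log2 scale (SE 0.25; adjusted p = 4.7e-07), and OsGA3ox2 (OS01G0177400), which makes the active hormone, rose by 1.03 (SE 0.15; adjusted p = 6.6e-06). OsKAO (log2 -0.31) and EUI1 (log2 -0.31) did not pass, though OsKAO did in replicates 2 and 3 alone (log2 -0.55, edgeR adjusted p = 9.6e-04). They stayed uncalled in 2 (OsKAO) and 3 (EUI1) of 6 other settings. Of the fits that left out 1 library, 6 called OsKAO and 7 called EUI1. Adjusted over the list alone, 5 of 7 gibberellin genes passed. Of 8 nitrogen genes, NADH-GOGAT2 (log2 -0.83, SE 0.16) and OsAMT1;1 (log2 -0.29, SE 0.10) fell and OsNRT1.1B (log2 0.58, SE 0.12), a nitrate transporter, rose, while Fd-GOGAT had a log2 value of 0.09; adjusted over the list alone 3 passed. The nitrogen list stood higher in replicate 1 by medians of 0.40 in GL and 0.63 in OE. Among 13 light input genes, OsPIL13 (log2 -0.53, SE 0.07), OsPIL15 (log2 -0.44, SE 0.07) and Se5 (log2 -0.44, SE 0.10) fell and OsPHYA (log2 0.29, SE 0.05) rose; in all 4 fell and 2 rose, and 7 passed when adjusted over the list alone. The call of OsAMT1;1 was lost in 12 of the fits that left out 1 library and with limma on FPKM at either pseudocount.

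Markers of other tissue states gave few calls. In the senescence list (6 tested) NYC1 (log2 0.27, SE 0.08) rose and OsPAO (log2 -0.35, SE 0.05) fell, both of chlorophyll breakdown, and OsPPH (log2 -0.25) and SGR (log2 0.24) did not pass, though SGR did in replicates 2 and 3 alone (log2 0.41, adjusted p = 2.0e-04); 5 passed when adjusted over the list alone. In the defence list (3 tested) OsWRKY45 rose (log2 0.47, SE 0.16), with its call lost in 9 of the fits that left out 1 library and with limma on log2(FPKM + 0.1), 1 passed over the list alone, and OsPR1a and OsPR1b had log2 values of 0.24 and 0.49. No member passed edgeR's test of the averaged contrast, over all genes or over the list alone, among 2 heat shock genes (OsHSP101 0.09, OsHSP18.0 -0.21), 2 cold response factors (OsDREB1A -0.50, OsDREB1G 0.83), 3 cell division genes (OsPCNA -0.18, CDKB2;1 0.26, CYCB1;1 0.13), 3 secondary wall cellulose synthases (OsCesA4 0.44, OsCesA7 0.82, OsCesA9 0.73) and 2 reference genes (OsActin1 0.07, OsUBC 0.07). At an unadjusted p under 0.05 only OsPCNA, 1 of these 12, was called, and DESeq2 and limma on FPKM called 0 of those they tested after adjustment. At single hours OsActin1 was called at 16:00, higher in OE (log2 0.66, SE 0.13; adjusted p = 0.0020). The defence list stood lower in replicate 1 than in the others, by medians of 0.801 (GL) and 1.33 (OE) log2 units. The call of NYC1 was lost with limma on FPKM. OsPPH stayed uncalled in 2 of 6 other settings and was called in 8 of the fits that left out 1 library. No meristem homeobox gene was high enough to be tested. The camera adjusted p values of the lists for light input, nitrogen, gibberellin, heat shock, cold, defence, senescence, cell division, secondary wall and reference genes lay between 0.65845 and 0.988. The secondary wall genes separated the replicates, with medians 1.73 (GL) and 1.87 (OE) log2 units higher in replicate 1 than in the others. At 16:00 their median was also 1.9 log2 units higher in OE, with 0 called (0.0101 to 0.903 at the other hours). OsPCNA, OsCesA7 and OsCesA9 stayed uncalled on average in 5 of 6 other settings. OsPCNA was called in 5 of the fits that left out 1 library.

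Over all 21772 genes tested, 5662 passed in the averaged contrast, 3052 higher and 2610 lower in OE, and 1032 of them changed at least 2-fold, 793 upward and 239 downward. Of loci with the same sign at all 6 hours, Rice_newGene_1309 (chromosome 12, 408003 to 409912) had 0 counts over the GL libraries and 3865 over the OE libraries, at least 1150-fold higher against a limit of 3 counts over the GL group. Rice_newGene_4790 rose from 0.0312 to 22.8 CPM, OS01G0748800 fell from 11.4 to 0.0451 CPM and OS03G0215400 fell from 10.7 to 0.185 CPM. In replicates 2 and 3 alone 6796 genes passed, of which 4788 were shared with the pooled list. With genotype and replicate number as a random block, which allows for libraries of 1 series being alike, 2225 passed. That fit used limma on voom values in place of edgeR. The effect of the block was not separated from that of the tool. The 6 series of a genotype and replicate number were also split otherwise, and setting GL replicates 1 and 3 with OE replicate 1 against the rest gave 6314 genes. In replicates 2 and 3 alone both other splits of the series gave 0.

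The hours were then compared separately. Calls numbered 975 at 4:00 (428 higher, 547 lower in OE), 721 at 8:00 (423 and 298), 439 at 12:00 (309 and 130), 1722 at 16:00 (1035 and 687), 547 at 20:00 (240 and 307) and 507 at 0:00 (279 and 228). Of 3087 genes called at 1 hour or more, 71 were called at all 6 hours, 2131 at exactly 1, and 53 with opposite signs at different hours. The 71 included OsPRR37, Ehd1, OsMADS14 and OsMADS18. In replicates 2 and 3 alone the counts were 1843 at 4:00, 1246 at 12:00, 3896 at 16:00, 1152 at 20:00 and 1183 at 0:00. With the replicate number as a block they were 1953, 1403, 1000, 3248, 1236 and 1088 from 4:00 to 0:00, and DESeq2 gave 706 at 12:00, 891 at 20:00 and 766 at 0:00. Single libraries mattered at 16:00, where leaving out GL replicate 1, 2 or 3 gave 814, 1065 or 1107 calls and leaving out OE replicate 1, 2 or 3 gave 2806, 825 or 811. Grouping the library with the conflicting genotype field as OE left 45 calls at 0:00.

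**Figure D4:**
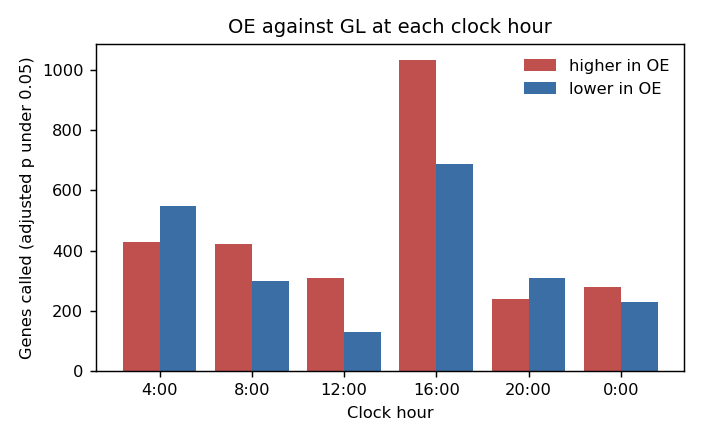
Number of genes higher (red) and lower (blue) in OE than in GL at each clock hour (adjusted p under 0.05, edgeR). The bars are highest at 16:00 (1035 higher, 687 lower) and lowest in total at 12:00 (309 and 130).

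The interaction test asks whether the OE effect depends on the hour, and 409 genes passed; 1022 did with the replicate number as a block, 845 with series as a random block, 1040 with DESeq2 and 1615 in replicates 2 and 3. OsPRR1 was higher in OE at 4:00 (10.04 ± 1.46 against 3.50 ± 0.313 CPM; SD, n = 3) and at 8:00 (log2 1.05, SE 0.15) and lower at its 16:00 peak (155 ± 14.7 against 213 ± 13.7 CPM; SD, n = 3). Hd1 was higher in OE at 8:00 (log2 1.81, SE 0.35) and 12:00 (log2 2.24, SE 0.42), the hours of its GL trough, while at 20:00 its log2 value was -0.99 without passing. OsDof12, a Dof factor that promotes flowering in long days, was lower at 16:00 (log2 -0.84, SE 0.15) and higher at 0:00 (log2 1.35, SE 0.17). DTH8, a subunit of a CCAAT-binding factor, was lower at 16:00 (log2 -0.76, SE 0.18). OsCOL10 fell by 2.40 at 20:00 and by 2.32 at 0:00 on the log2 scale, and its values at 8:00 and 12:00 (-0.48 and -0.52) did not pass. OsGBSSII showed its largest fall at 0:00 (log2 -3.13, SE 0.38), and the antenna gene OS06G0320500 fell by 1.35 at 4:00 and by 1.82 at 0:00, against -0.16 at 8:00, which did not pass. Leaving out GL replicate 2, OE replicate 2 or OE replicate 3 at 16:00 gave 262, 249 or 268 interaction calls, and leaving out OE replicate 1 at 16:00 gave 724.

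Most leaf transcripts changed over the day in both genotypes. In GL 15179 genes and in OE 14941 passed the test of change among the 6 hours, 13411 in both. The 24-h harmonic passed for 15632 genes in GL and 15334 in OE, 13682 in both. Fitted peaks fell most often nearest 8:00, with 19.36% of GL and 18.98% of OE rhythmic genes, and least often nearest 12:00 in GL (13.6%) and nearest 4:00 in OE (12.9%). Among genes rhythmic in both, the OE peak was later by a median of 0.19 h (quartiles -0.37 and 0.73 h), which is less than its leave-one-library-out error of 0.29 h. Passing in 1 genotype alone does not show a difference, so rhythm was compared directly, and 20 genes passed: 11 had a smaller and 9 a larger fitted range in OE. OsPRR37 passed. So did OsPRR1, whose range was 5.45 log2 units in GL and 3.75 in OE, and OsCOL10, with 4.05 and 6.19. OS03G0303100 (5.38 and 1.92) and OS09G0128400 (5.39 and 3.03) lost range, and OS12G0489400 (1.85 and 4.26) and OS01G0905200 (0.84 and 3.17) gained it. The count was 109 with DESeq2, 45 with the replicate number as a block and 33 with series as a random block. In replicates 2 and 3 alone 38 genes passed; leaving out GL replicate 1 or OE replicate 3 at 8:00 gave 35 or 33, and leaving out GL replicate 2 at 16:00 gave 13.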

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

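The splits of whole series were chosen after the results were seen. So were the tests of the replicate split (its sharing between genotypes, wall tissue and its part in the genotype calls). Tests of 2 explanations of the OE-only loci's placement, of plant-to-plant state and of spread at 16:00 were also chosen then. The test of a sampling offset at 16:00 was aimed at that hour for its number of calls, so it too followed the hourly counts. The splits of single libraries were chosen before.

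The effect of OE differed between hours, by the genotype by hour interaction (edgeR, adjusted p), for OsPRR37 (1.7e-18), OsPRR1 (5.5e-06), OsPRR59 (0.011), OsPRR95 (0.032), OsDof12 (5.0e-05), DTH8 (0.031), OsCOL4 (0.011), OsCOL10 (5.5e-04), Hd1 (5.5e-04), OsPIL13 (0.0021) and OsGBSSII (0.033). It also differed for the antenna gene OS06G0320500 (0.034) and for OS03G0303100 (6.1e-05), OS09G0128400 (6.8e-05), OS12G0489400 (0.0012) and OS01G0905200 (0.011). OsPIL13 fell most at 16:00 (log2 -1.49, SE 0.19) and OsCOL4 at 20:00 (log2 -2.04, SE 0.26).

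Other groupings of the libraries were drawn to ask how often chance gives as many calls. For the averaged contrast, the interaction and the rhythm difference, genotype was exchanged within hours, and only 1 of 50 splits, the real one, reached the real counts of 5662, 409 and 20; the highest others were 30, 94 and 5. For the change over the day the hours were exchanged within a genotype, and again 1 of 50 splits reached 15179 (GL) and 14941 (OE), with 243 and 298 as the highest others. For the 24-h rhythm 1 of 50 reached 15632 (GL) and 15334 (OE), with 22 and 1064 as the highest others. No other split of single libraries reached the real count for these 7 results. For the genotype results this cannot exclude chance differences between whole series. These splits break up the series of 1 genotype and replicate number, whose libraries are alike (correlation 0.195), so the genotype results were also set against all 10 splits of the 6 whole series, too few for a share under 0.05. For the averaged contrast 2 of 10 splits, the real one among them, gave as many genes. Setting GL replicates 1 and 3 with OE replicate 1 against the rest gave 6314, above the real 5662. This split puts replicate 1 of both genotypes on the same side. With the replicate number as a block the real split gave 7153 and the highest other 1342, with series as a random block 2225 and 1765, and in replicates 2 and 3 alone 6796 and 0. For the interaction and the rhythm difference 1 of 10 splits of the series, the real one, gave as many, with 1 and 2 as the highest others. At a single hour 3 against 3 libraries make 10 splits, too few for a share under 0.05. The real and highest other counts were 975 and 2 (4:00), 721 and 4 (8:00), 439 and 2 (12:00), 1722 and 181 (16:00), 547 and 0 (20:00), and 507 and 1 (0:00), with 1 split as large in each.

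The excess of calls at 16:00 was weighed against sampling and noise. Had OE leaves been cut earlier or later than GL leaves at that hour, folds would follow the slope of each gene over time. With slopes from GL replicate 1 and folds from replicates 2 and 3, over 13166 rhythmic genes, the slope explained an R squared of 0.000256 and implied an offset of 0.0525 h, which argues against an offset shared by the OE libraries as the cause; replicates 2 and 3 taken singly gave -0.229 and 0.334 h, so offsets of single libraries stay open. Smaller spread or greater depth is argued against as well: mean depth at 16:00 (12.41 M counts) was not the highest, within-group spread (0.249) was not the lowest, and the SD of folds over genes (0.678) exceeded that at every other hour (0.553 to 0.638). A response to OsPRR37 that is widest in the afternoon remains open as a hypothesis and was not tested. The reference gene OsActin1 was also higher in OE at that hour (log2 0.66). So was the median of the 3 secondary wall genes (log2 1.9), with 0 of them called. The count also rests on single libraries, from 811 without OE replicate 3 to 2806 without OE replicate 1.

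Replicate 1 stood apart in both genotypes. Its difference from replicates 2 and 3 correlated between GL and OE across 16799 genes with r = 0.801 (Spearman 0.731; genes are not independent replicates), which is consistent with a batch or day shared by both genotypes. The secondary wall genes OsCesA4, OsCesA7 and OsCesA9 were higher in replicate 1 by medians of at least 1.73 (log2) in each genotype. OsCesA4 had mean levels of 5.97, 1.88 and 3.38 CPM in GL replicates 1 to 3 and 7.87, 4.14 and 2.58 CPM in OE, so more vein or sheath tissue in those leaves may contribute, though 3 genes of 1 complex leave growth stage open. Genotype calls did not need replicate 1, since 6796 genes passed in replicates 2 and 3 alone. Of the averaged calls, 84.6% passed there with the same sign. These libraries also took part in the averaged calls, so that overlap is partly built in. It cannot tell how far replicate 1 shaped the averaged calls.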

How the results depend on the processing

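Fits on replicates 2 and 3 only and on counts reduced by 1 were chosen after the data were seen; the other alternatives were fixed before the data were examined. Unless stated, the cause of a change was not tested. The OsPRR37 fold (4.05 to 4.42 log2 units under other settings, 4.38 to 4.45 with a library left out), the counts for change over the day and 24-h rhythm in either genotype, and the peak hour shift (0.1459 to 0.1948 h; 0.0830 to 0.286 h with a library left out) kept their call or stayed within 1.5 times or their error. DESeq2 size factors, no filter, limma on FPKM with either pseudocount and counts reduced by 1 moved no count by over 1.5 times. The share of averaged calls higher in OE was 53.9%, and 48.8% to 54.6% under the other settings. DESeq2 called 706 genes at 12:00, 891 at 20:00, 766 at 0:00, 1040 for the interaction and 109 for the rhythm difference. The replicate block called 1953 at 4:00, 1403 at 8:00, 1000 at 12:00, 3248 at 16:00, 1236 at 20:00, 1088 at 0:00, 1022 for the interaction and 45 for the rhythm difference, and 7153 on average. Same-numbered GL and OE libraries correlated above 0.1 in 16 of 18 pairs (lowest 0.064), and 15 of 18 correlated best with their own number, a hint from the data that the design does not state. Genotype and replicate number as a random block (correlation 0.195) called 2225 on average, 845 for the interaction and 33 for the rhythm difference. These 3 counts are from limma on voom values, so they differ from the main counts in tool as well as in block. Replicates 2 and 3 only gave 1843 at 4:00, 1246 at 12:00, 3896 at 16:00, 1152 at 20:00, 1183 at 0:00, 1615 for the interaction and 38 for the rhythm difference, and moved the starch list to an adjusted p of 0.01751. A threshold of 0.01 left, by its construction, 3523 on average, 497, 264, 209, 655, 260 and 272 from 4:00 to 0:00, 159 for the interaction and 8 for the rhythm difference. At least 2-fold changes numbered 1032 on average and 513, 374, 272, 880, 325 and 314 from 4:00 to 0:00. Models of the 6 libraries of 1 hour, with fewer samples to estimate spread, called 209, 244, 161, 400, 360 and 257. Grouping the GL library with the conflicting label as OE left 45 calls at 0:00. An estimated correlation ended the list calls for light harvesting (0.1745), chlorophyll synthesis (0.54284) and jasmonate (0.21261). For the starch list it gave 0.82763 over all libraries. It was not run in replicates 2 and 3 alone.

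With each library left out in turn, counts ran from 5176 to 6170 on average, 544 to 1051 at 4:00, 370 to 792 at 8:00, 268 to 533 at 12:00, 811 to 2806 at 16:00, 277 to 630 at 20:00, 301 to 569 at 0:00, 249 to 724 for the interaction, 14689 to 15474 and 14315 to 15267 for change over the day in GL and OE, 15204 to 15801 and 14846 to 15607 for their rhythms, and 13 to 35 for the rhythm difference. Beyond those named for 16:00, the interaction and rhythm, counts moved by over 1.5 times without OE replicate 3 at 4:00 (544), GL replicates 1 and 2 and OE replicate 3 at 8:00 (423, 402, 370), GL replicate 2 and OE replicates 2 and 3 at 12:00 (270, 268, 269), GL replicate 2 and OE replicates 2 and 3 at 20:00 (286, 280, 277), and GL replicates 1 and 2 and OE replicate 3 at 0:00 (310, 301, 328). Of 87 named genes besides OsPRR37, 53 were called on average; 44 kept the call with each library left out, DESeq2 size factors, DESeq2, limma on FPKM, the replicate block and replicates 2 and 3 only, and 9 lost it in at least 1: DTH2, OsCO3, Hd1, OsWRKY45, OsAOS2, OsJAZ11, OsJAZ12, OsAMT1;1 and NYC1. None of the 53 changed sign. Of the named genes not called on average, 9 became called in at least 1 fit with a library left out. In the remaining settings just listed, 12 became called in at least 1. Results of single genes under the other settings are not given here. Those settings include genotype and replicate number as a random block, which called 2225 genes on average. How many of the 44 kept their call there is not reported. At a threshold of 0.01 OsPRR95 (adjusted p = 0.012), OsMADS56 (0.016) and OsDVR (0.018), among others, would not pass. Depth limits genes under about 1 CPM, such as OsMADS15 and OsPR1a, to coarse folds.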

Other observations

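The tests on the OE-only loci were chosen after the result was seen. The time of day at which a gene peaks in GL went with its direction in OE. Peak hours were fitted in GL replicate 1 alone and calls taken from replicates 2 and 3 alone, so peak hour and call come from separate libraries. The choice of rhythmic genes used all replicates, among them those that gave the calls. Of 2366 rhythmic genes that peaked nearest 8:00, 35.9% fell and 10.4% rose in OE. Of 2201 that peaked nearest 4:00, 506 fell and 316 rose, and of 1830 nearest 12:00, 400 fell and 310 rose. Among 2358, 2330 and 2081 genes that peaked nearest 16:00, 20:00 and 0:00, 237, 275 and 259 fell while 438, 449 and 499 rose. Median log2 changes from the 4:00 to the 0:00 group were small, at -0.0546, -0.111, -0.0157, 0.026, 0.0221 and 0.0141. No test of this association was run.

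The OE folds followed in part the slope of each gene over time at 4:00 and 0:00. The folds at 4:00, regressed on the slope of each gene over time in GL replicate 1, gave an implied offset of OE relative to GL of -1.03 h (R squared 0.139), and those at 0:00 gave -0.939 h (R squared 0.082). The value held in replicates 2 and 3 taken singly (-1.05 and -1.02 h at 4:00; -0.861 and -1.02 h at 0:00), while replicate 3 against replicate 2 within a genotype gave between -0.0647 and -0.258 h at these hours. At 12:00 and 20:00 the implied values were 0.387 and 0.306 h, and at 8:00 -0.161 h. Most of the variance of the folds was not explained, and no test told a lag from sampling times or from changed ranges.

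Among loci near silent in GL (mean under 0.2 CPM) and at least 8-fold higher in OE, 53 passed, against 8 in the opposite direction. Of the 53, 25 were loci that the authors' files call new genes, as were 2 of the 8. A few chromosome segments from another variety would place them in blocks, but they lay on 12 chromosomes, and 12.0% of 50 sites, tandem neighbours merged, had another within 500 kb, against a median of 15.1% in 1000 random sets, which argues against that cause but leaves scattered variants open. Reads of the transgene placed elsewhere are argued against for 6 loci, which in OE replicate 3 had a mean under 10% of both other replicates, although OsPRR37 stood at 1136, 1190 and 1195 CPM in OE replicates 1 to 3; for the other 47, which no OE replicate had so far below both others, they cannot be told apart from transcription at the locus. Of the 6 loci (11.3%), 3 lay below both other replicates at all 6 hours, and such loci may mark sites whose transcription differs between plants of the OE line; with 8 loci to compare in GL this cannot be told apart from chance or from the handling of the line.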
